A study of Homo sapiens with 15 samples.

How the data were processed

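Bulk RNA sequencing was done on human umbilical vein endothelial cells (HUVEC), primary cells from the lining of the umbilical vein. The 15 libraries form 5 groups of 3: vehicle (DMSO) and FK866 at day 2, DMSO and FK866 at day 5, and FK866 with NMN at day 5. FK866 inhibits NAMPT, the enzyme that recycles nicotinamide into the NAD precursor nicotinamide mononucleotide (NMN), so that NMN supplies the product that the inhibited enzyme would make. Per the labels, FK866 was given at 20 nM from seeding, cultures were sparse at day 2 and usually confluent by day 5, and RNA was taken with TRIzol, checked for integrity on a TapeStation and made into libraries with a NEBNext Ultra II RNA kit. The dose of NMN is not given in the sources used here. The labels do not say that the replicates of a group are separate cultures or donors, so each p-value measures only the spread between these libraries.

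The authors deposited a single table in TPM, a transcript abundance in which each gene's reads are divided by its length and each library is scaled to the same total. The processing notes name the GRCh38 genome, FastQC, Picard, STAR 2.7.9a and limma 3.60.6 without the role of each, and the tool that computed TPM is not given in the sources used here. The table lists 15085 genes, 834 of them annotated as pseudogenes, and each of its 15 columns adds up to 1000000. The sum is the same for every library, so the depth is unknown, and no counting interval or detection limit can be given. Genes coding for 8 ribosomal RNAs are part of the table and of its total. An exact 0 is listed in 254 places, in 133 genes. A symbol is given for 14025 genes and not for the other 1060, of which 838 had no symbol in a local annotation table either and keep their Ensembl identifiers. Coordinates are those of the deposited table. The mitochondrially encoded transcripts are not analysed here.

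Genes with a TPM of at least 1 in at least 3 libraries were tested, 14721 in all. Values were converted to log2(TPM + 1), so that fold changes of genes near 1 TPM are understated. A single model with 5 group means was fitted with limma 3.58.1 in R 4.3.3, with an intensity trend in the variance prior. The fit left 10 residual degrees of freedom, to which the prior added 4.72. The spread of each gene was thus shared by all 5 groups. All tests were two-sided except Fisher's exact test of list enrichment, which was one-sided. For single genes, p-values were adjusted by Benjamini-Hochberg over the genes of each of the 7 comparisons: FK866 against DMSO at day 2 and at day 5, FK866 with NMN against FK866 and against DMSO at day 5, day 5 against day 2 in DMSO and in FK866, and the difference between the FK866 effects at day 5 and at day 2. A gene was called at an adjusted p under 0.05. Changes are log2 fold changes with their standard error from the model (SE), and levels are mean TPM ± SD with 3 libraries per group. Genes linked to sex, 14 in number, were tested with the others and left out of every value given for a single gene.

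Gene lists were fixed before the data were examined: 41 in all, of which 36 had at least 5 tested members. They cover NAD and redox metabolism, energy metabolism, the cell cycle, stress responses, endothelial genes, signalling pathways, matrix, ribosomal proteins and markers of other cell types. Each was tested with fry and with camera on log2(TPM + 1) values, with p-values adjusted over the lists of a comparison. Fry tests whether the genes of a list move one way on balance and compares them with no other set. Camera was run with a correlation estimated from the data for each list. Calls of list members are also given adjusted over the list alone. The genes named in the text follow a rule fixed before the data were examined: NAMPT, up to 8 called genes with the largest increase and 8 with the largest decrease per comparison (5 and 5 for the difference of effects) among the more abundant genes with an official symbol and no overlap between the groups, and the list members with the largest changes. Genes named outside this rule are identified as such.

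The tests were also run on simulated data of the same size, with a single pooled spread per gene for all groups and independent noise in each library. In the real data the median SD of a gene on the log2 scale ran from 0.07 (FK866 with NMN) to 0.37 (DMSO at day 5). The shares recovered therefore describe the fitted model and need not hold for each real comparison. For FK866 against DMSO at day 5 the tests recovered 16.9% of genes changed by 1.5-fold, 70.7% at 2-fold and 100% at 4-fold, with 6 false calls among 130. At day 2 the shares were 13.6%, 71.4% and 100%, with 7 false calls among 130. For the difference of effects they were 6.06%, 14.5% and 95.8%, with 3 false calls among 85.

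Alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.5, no filter on low values, no intensity trend, a test against a 1.5-fold change, a fit of only the groups compared, the replicate number as a block, and leaving out each library in turn. Alternatives added after the data were seen were median-of-ratios scaling, removal of the ribosomal RNA genes before rescaling, leaving out both day 5 libraries numbered 1, combinations of these, a minimum of 5 TPM in 3 libraries and, for gene lists, a fit of only the groups compared. The replicate block was fitted to only the groups compared. Median-of-ratios scaling divides each library by the median ratio of its genes to their mean over all libraries.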

Results

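The series concerns NAD-dependent redox control in endothelial cells that leave the cell cycle as a culture becomes confluent. The libraries separated first by day and treatment. In a principal component analysis, the first component held 71.9% of the variance and the second 14.6%. All 6 day 2 libraries lay between -68.4 and -57.7 on the first component. The FK866 libraries of day 5 lay between -18.8 and 21.4, the DMSO libraries of day 5 between 30.5 and 67.0, and the libraries of FK866 with NMN between 75.4 and 75.8. At day 5 the DMSO library numbered 1 (75.1) and the FK866 library numbered 1 (45.5) stood apart on the second component. The DMSO library numbered 1 correlated across genes at r = 0.931 with each of the other DMSO libraries of day 5, which correlated at 0.996 with each other. The median SD of a gene on the log2 scale was 0.37 in DMSO and 0.25 in FK866 at day 5, against 0.10 and 0.16 in the same treatments at day 2 and 0.07 with NMN.

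**Figure D1:**
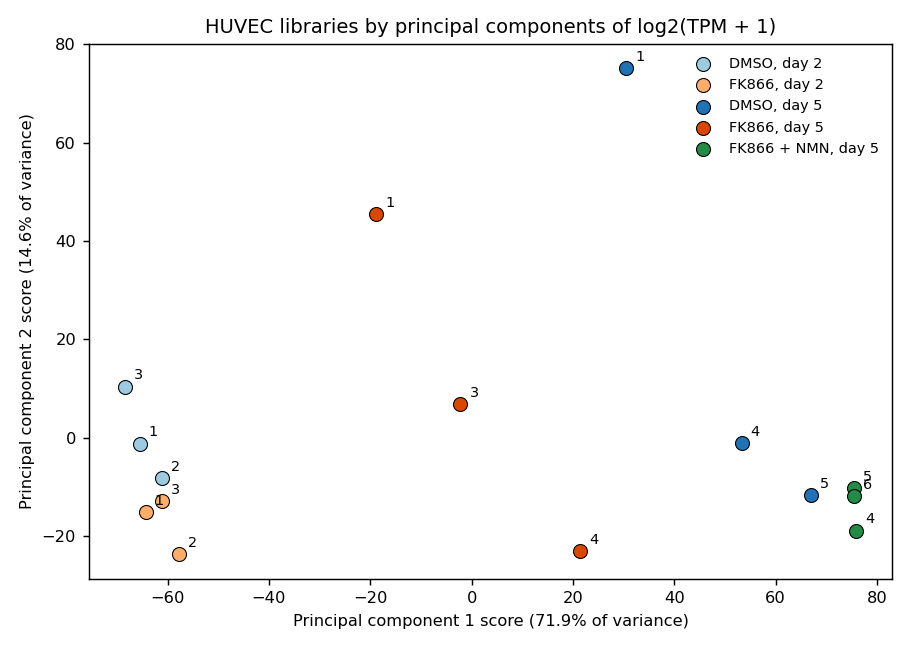
The 15 libraries on the first principal component (horizontal axis, 71.9% of the variance) and the second (vertical axis, 14.6%), one point per library, labelled with its replicate number and coloured by group. The day 5 libraries numbered 1 lie at 75.1 (DMSO) and 45.5 (FK866) on the second component.

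Ribosomal RNA genes took 4.98% ± 0.816 of the TPM in DMSO at day 2 (mean ± SD, n = 3 per group), 14.6% ± 10.3 in FK866 at day 2, 18.0% ± 13.1 in DMSO at day 5, 8.55% ± 2.54 in FK866 at day 5 and 4.70% ± 0.364 with NMN. A larger share of these genes lowers the TPM of every other gene in a library. Median-of-ratios scaling, which removes such a shift, is therefore given beside each comparison. No single list called by fry reversed its direction under that scaling in any comparison other than that of FK866 with NMN against DMSO. No list passed camera with an estimated correlation in any comparison, and its lowest adjusted p was 0.0996, for DNA replication between day 2 and day 5 in FK866.

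NAMPT (ENSG00000105835, GRCh38 chromosome 7, 106248298 to 106285966), which encodes the enzyme that FK866 inhibits, did not pass the threshold in any of the 7 comparisons in the main fit. Its level was 25.5 ± 2.85 TPM in DMSO and 22.5 ± 2.54 in FK866 at day 2, 26.0 ± 9.75 and 38.1 ± 12.6 at day 5, and 34.4 ± 1.61 with NMN (SD, n = 3). The log2 fold change of NAMPT for FK866 was -0.17 ± 0.26 at day 2 (SE, adjusted p = 0.813) and 0.55 ± 0.26 at day 5 (adjusted p = 0.127). At day 5 it passed without the DMSO library numbered 5 (0.79, adjusted p = 0.0378) or the FK866 library numbered 1 (0.79, adjusted p = 0.0386), and without both libraries numbered 1 (0.47, adjusted p = 0.029). It also passed with the replicate number as a block, by the description number (0.55 ± 0.14, SE, adjusted p = 0.0158) and by the title number (libraries 1 and 4, 0.79 ± 0.27, adjusted p = 0.0243), so its change at day 5 stays unsettled. With NMN it was -0.09 against FK866 (adjusted p = 0.782), or -0.51 (adjusted p = 0.000693) under median-of-ratios scaling without the day 5 libraries numbered 1, and 0.46 against DMSO (adjusted p = 0.16), where it passed without the DMSO library numbered 5 (0.70, adjusted p = 0.0375). Without the day 5 libraries numbered 1 the difference of FK866 effects on NAMPT passed too (0.64, adjusted p = 0.0202, and 0.37, adjusted p = 0.0395, after scaling). The inhibitor acts on the enzyme, so the mRNA level says nothing of the inhibition itself. The pseudogene NAMPTP1 had levels close to those of NAMPT in each library, and whether they share reads is not known.

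The change from sparse culture at day 2 to day 5 was examined first in DMSO. AQP1 (ENSG00000240583, chromosome 7, 30911853 to 30925517), a water channel of endothelium, rose from 1.81 to 543 ± 109 TPM (SD, n = 3), a log2 fold change of 7.61 ± 0.25 (SE, adjusted p = 2.37e-11). GJA4, a connexin of arterial gap junctions, rose by 6.20 ± 0.19 (adjusted p = 1.6e-11), and IL33, a nuclear alarmin of resting endothelium, by 6.19 ± 0.35 (adjusted p = 3.92e-09). ACE, the angiotensin-converting enzyme, rose by 5.45 (adjusted p = 3.9e-11) and the TGF-beta family ligand GDF3 by 5.23 (adjusted p = 5.12e-11). The glycosyltransferase GALNT15 rose by 5.14 (adjusted p = 3.28e-10) and the death ligand TNFSF10 by 5.14 (adjusted p = 1.47e-11). COL1A2 (ENSG00000164692, chromosome 7, 94394895 to 94431227), a chain of type I collagen, rose from 1.78 to 83.3 ± 12.9 TPM, by 4.91 (adjusted p = 1.6e-11). DKK1, a secreted Wnt inhibitor, fell from 757 ± 34.4 to 73.8 ± 11.4 TPM, a change of -3.35 ± 0.13 (adjusted p = 2.03e-10). Further falls were those of G0S2, an inhibitor of lipolysis (-3.24), the long noncoding RNA LNCOG (-3.20), and the metallothionein MT1A (-3.19, with near-identical paralogs). The ubiquinone pathway enzyme HPDL (-3.16), the AP-1 subunit FOSL1 (-3.16), the IL-33 receptor IL1RL1 (-3.15) and the G protein regulator RGS4 (-3.13) fell as well. Adjusted p for these 7 genes ran from 3.29e-10 (IL1RL1) to 4.17e-06 (MT1A). In all, 4364 genes rose and 4274 fell, of which 2145 and 1795 changed at least 2-fold. Median-of-ratios scaling gave 5252 and 4081 and moved the median of all genes from 0.04 to 0.12, and removal of the ribosomal RNA genes gave 5658 and 3550.

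Proliferation genes fell in DMSO between day 2 and day 5. All 33 tested DNA replication genes fell (33 adjusted over the list alone), among them UHRF1 (-3.01, adjusted p = 2.26e-09), E2F1 (-3.01, adjusted p = 9.95e-08) and CDC6 (-2.98, adjusted p = 8.7e-10), with a list median of -2.17 relative to all genes (fry adjusted p = 1.83e-08, adjusted p = 0.226 with an estimated correlation). Of 31 mitosis genes 30 fell (31 adjusted over the list alone), such as AURKB (-2.83) and CDC20 (-2.82), at a relative median of -2.19 (fry adjusted p = 6.28e-08). Ribosome biogenesis and MYC targets fell in 22 of 23 (23 adjusted over the list alone), led by ODC1 (-2.62) and NOP16 (-2.23), at -1.57 (fry adjusted p = 7.49e-08). Both lists had adjusted p = 0.226 with an estimated correlation. Of 21 glycolysis genes 17 fell and 2 rose, the same adjusted over the list alone, with LDHA at -2.18 and HK2 at -1.96 (fry adjusted p = 1.1e-05). The TCA cycle fell in 19 of 21, as in FH (-1.83) and IDH3A (-1.38). The pentose phosphate and NADPH list fell in 13 of 15 and rose in 1, as in MTHFD1 (-1.80) and MTHFD2 (-1.69). Cholesterol synthesis fell in 14 of 20, as in ACAT2 (-1.87). Each had the same count adjusted over the list alone, with fry adjusted p from 6.21e-06 to 1.1e-05. NRF2 targets fell in 12 of 18, as in OSGIN1 (-2.25) and NQO1 (-2.08), while 2 rose (fry adjusted p = 2.16e-05). These 5 metabolic and NRF2 lists had adjusted p = 0.366 with an estimated correlation. The nuclear-encoded respiratory chain fell in 17 of 32 (CYCS -1.76, fry adjusted p = 0.0119). The ATF4 and amino acid response fell in 17 of 24 while 5 rose (SLC7A5 -2.61, DDIT4 2.54, fry adjusted p = 0.000191). Senescence and secretory genes fell in 7 of 13 while 2 rose (CXCL8 -2.87, MMP1 -2.30, fry adjusted p = 7.62e-05). YAP and TAZ targets fell in 6 of 18 while 2 rose (AXL -2.48, fry adjusted p = 0.0166), a call lost without the ribosomal RNA genes (0.0681), without the day 5 libraries numbered 1 (0.101, 5 up and 6 down, list median 0.02) and with the replicate block (0.329). With the replicate number as a block in a fit of only the groups compared, which keeps the fold changes and has fewer degrees of freedom, every fry call of this comparison was lost. The adjusted p then ran from 0.0568, as for DNA replication, mitosis and ribosome biogenesis, to that 0.329. In the same fit without the block only those for the respiratory chain (0.0982), YAP and TAZ targets (0.112) and lysosome and autophagy genes (0.0581) were lost.

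Endothelial lists rose in DMSO over the same interval, and none of their fry calls held with the replicate block (lowest adjusted p = 0.0568, arterial genes). That block pairs libraries by number, a pairing that the labels do not state and that the deviations over time do not show. Endothelial identity genes rose in 13 of 21 and fell in 1 (13 and 1 adjusted over the list alone), with CD34 at 4.76 and VWF at 3.52, at a relative median of 1.23 (fry adjusted p = 2.45e-06). Arterial genes rose in 9 of 13 with 1 fall, led by GJA4 and SEMA3G (4.82), at 1.51 (fry adjusted p = 1e-07). Venous and lymphatic genes rose in 6 of 7 (LYVE1 4.12, FLT4 2.40, fry adjusted p = 2.87e-06). Notch signalling rose in 10 of 14 with 1 fall (DLL4 3.70, DLL1 3.42, fry adjusted p = 2.11e-06) and extracellular matrix genes in 16 of 24 with 1 fall (MGP 3.55, fry adjusted p = 6.21e-06). Interferon response genes rose in 17 of 22 and fell in 2 (CXCL11 2.59, IFIH1 2.33, fry adjusted p = 2.68e-05). These 6 lists had adjusted p = 0.366 with an estimated correlation. Endothelial junctions rose in 11 of 19 with 1 fall (GJA5 3.39), shear and quiescence regulators in 10 of 14 with 1 fall (TFPI 3.40) and FOXO targets in 11 of 16 with 2 falls (PDK4 4.52, BCL2L11 3.54). Cell cycle inhibitors rose in 8 of 15 with 3 falls (CDKN1C 3.80, BTG2 3.10), inflammatory activation genes in 13 of 21 with 5 falls (CXCL2 2.28) and BMP and ALK1 signalling in 6 of 11 with 2 falls (BMP4 1.69). These 6 lists had fry adjusted p from 2.48e-05 (junctions) to 0.00351 (BMP and ALK1). Smaller shares rose among p53 targets (8 of 22 with 4 falls, TP53INP1 3.57, fry adjusted p = 0.008), lysosome and autophagy genes (9 of 22 with 2 falls, ULK1 1.41, fry adjusted p = 0.00849) and NAD synthesis and transport (3 of 12 with 1 fall, fry adjusted p = 0.00533). In the last list NMRK1, a kinase that makes NMN from nicotinamide riboside, rose by 2.32 (adjusted p = 7.12e-09).

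Inhibition of NAMPT at day 2, in sparse culture, gave few calls. TXNIP, an inhibitor of thioredoxin and of glucose uptake (ENSG00000265972, chromosome 1, 145992435 to 145996579), rose from 17.5 ± 1.49 TPM in DMSO to 38.6 ± 4.28 in FK866 (SD, n = 3), by 1.10 ± 0.16 (SE, adjusted p = 0.0436). EGR1, an immediate early transcription factor, rose from 3.21 ± 0.51 to 7.54 ± 1.32 TPM, by 1.02 ± 0.16 (adjusted p = 0.0487). The 3 genes that fell were outside the rule for naming genes and chosen after their values were seen. FST, an activin-binding protein, fell from 39.8 ± 3.01 to 16.9 ± 2.50 TPM (-1.20, adjusted p = 0.0441). KRT7-AS, an antisense RNA of the keratin gene KRT7, fell from 17.9 to 7.44 TPM (-1.17, adjusted p = 0.0441), and the unnamed gene ENSG00000275180 from 24.2 to 10.8 TPM (-1.11, adjusted p = 0.0436). Whether the reads of KRT7-AS are separable from those of KRT7 is not known. Thus 5 genes passed (2 up, 3 down), and 1467 had an unadjusted p under 0.05. No list passed fry (lowest adjusted p = 0.881), and TXNIP, in the FOXO and shear lists, was the 1 list member that passed over all genes. Median-of-ratios scaling called 134 genes (38 up, 96 down), and a fit of the day 2 groups alone called 2530 (662 up, 1868 down), where the spread no longer includes the day 5 libraries. The excess of falls did not hold under the other scaling, where the same fit called 4540 (2393 up, 2147 down). Leaving out any 1 of the 6 libraries gave no calls at all, with 800 to 1682 genes at an unadjusted p under 0.05 in limma.

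FK866 was next compared with DMSO at day 5, when cultures were usually confluent per the labels. Cell density, NAD level and NAMPT activity were not measured here. An effect of the inhibition thus cannot be told apart from a difference in density between the treatments. MMP1, an interstitial collagenase (ENSG00000196611, chromosome 11, 102789401 to 102798160), rose 9.02-fold, from 59.8 ± 4.22 TPM in DMSO to 547 ± 45.7 in FK866 (SD, n = 3), a log2 fold change of 3.17 ± 0.12 (SE, adjusted p = 1.46e-09). GDF15, a stress-induced cytokine (ENSG00000130513, chromosome 19, 18374731 to 18389176), rose 7.60-fold, from 82.9 ± 13.9 to 631 ± 38.7 TPM (adjusted p = 1.15e-08). COL1A2 fell from 83.3 ± 12.9 to 10.2 ± 1.19 TPM, a change of -2.90 ± 0.15 (adjusted p = 2.02e-08). AQP1 fell from 543 ± 109 to 110 ± 45.6 TPM, a change of -2.34 ± 0.25 (adjusted p = 1.6e-05), and GJA4 from 110 ± 30.6 to 19.4 ± 1.95 TPM, a change of -2.40 ± 0.19 (adjusted p = 1.5e-06).

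Other increases at day 5 were in IL1RL1, the IL-33 receptor (2.85 ± 0.13, adjusted p = 6.18e-09, 21.8 to 164 TPM), and PLEK2, a membrane-binding protein of the actin cytoskeleton (2.47 ± 0.32, adjusted p = 7.03e-05). LNCOG rose (2.42 ± 0.18, adjusted p = 7.52e-07), as did FOSL1 (2.42 ± 0.21, adjusted p = 3.27e-06, 43.7 to 228 TPM), the neutrophil chemokine CXCL8 (2.27 ± 0.18, adjusted p = 1.22e-06, 8.92 to 47.4 TPM) and MT1A (2.07 ± 0.37, adjusted p = 0.00088). MT1A lost its call in a fit of only the groups compared with median-of-ratios scaling (1.95 ± 0.54, adjusted p = 0.0809). Other decreases were in IL33 (-2.50 ± 0.35, adjusted p = 0.000124, 98.9 to 17.1 TPM) and SEMA3G, a semaphorin of arterial endothelium (-2.39 ± 0.29, adjusted p = 4.29e-05, 46.7 to 8.03 TPM). Decreases also appeared in the matrix protein MATN2 (-2.19 ± 0.27, adjusted p = 5.32e-05), the zinc transporter SLC30A3 (-2.10 ± 0.25, adjusted p = 4.29e-05) and GALNT15 (-2.05 ± 0.22, adjusted p = 1.6e-05). All 3 FK866 libraries lay on the same side of all 3 DMSO libraries for each of these genes, which the naming rule required of them. In all, 2599 genes rose and 1372 fell, with 578 and 384 at least 2-fold. Median-of-ratios scaling gave 2269 and 2620 and moved the median of all genes from 0.08 to -0.04, with 3569 genes called in the same direction under both. Removal of the ribosomal RNA genes gave 2261 up and 2565 down. The number of calls depended on single libraries: it was 6416 without the DMSO library numbered 1 and 2638 without the FK866 library numbered 3. It fell to 687 (466 up, 221 down) in a fit of only the groups compared, and to 1127 (537 up, 590 down) in that fit with median-of-ratios scaling.

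**Figure D2:**
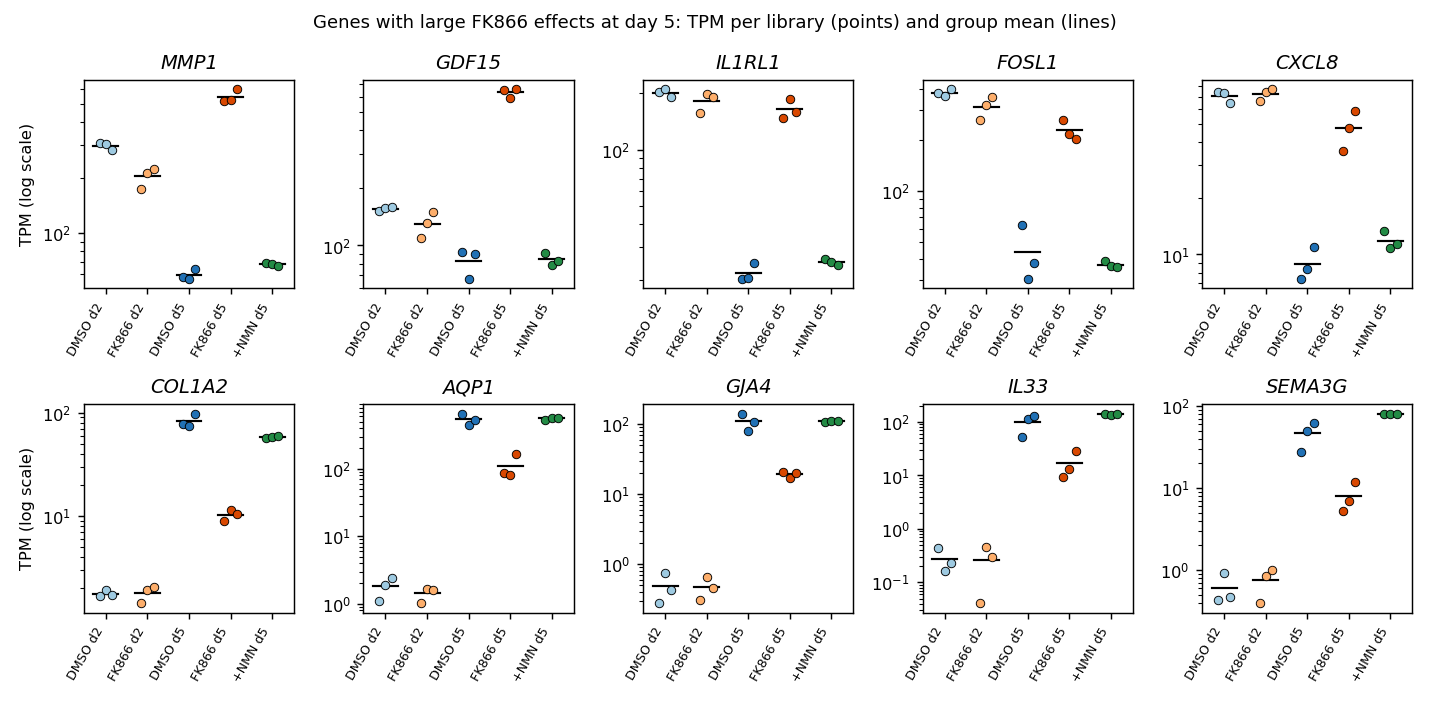
TPM on a log axis in each of the 5 groups for 5 genes that rose in FK866 at day 5 (top) and 5 that fell (bottom), with one point per library and a line at each group mean. MMP1 averages 59.8 TPM in DMSO, 547 in FK866 and 68.2 in FK866 with NMN at day 5.

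Stress and redox lists rose with FK866 at day 5. Of 18 NRF2 targets, which respond to oxidants and electrophiles, 13 rose and 1 fell (14 and 1 adjusted over the list alone), led by OSGIN1 (2.51, adjusted p = 8.35e-06), SRXN1 (1.87) and NQO1 (1.73). The list had a median of 0.87 relative to all genes (fry adjusted p = 4.01e-05, adjusted p = 0.314 with an estimated correlation). ATF3, a stress-induced transcription factor, rose from 2.92 ± 0.54 to 67.8 ± 17.6 TPM (4.12, adjusted p = 4.87e-09). It headed the ATF4 and amino acid response, in which 11 of 24 rose and 3 fell (12 and 3 adjusted over the list alone), with SLC3A2 at 1.58 and NUPR1 at -1.37 (fry adjusted p = 0.000906, adjusted p = 0.583 with an estimated correlation). Of 22 p53 targets, 12 rose and 2 fell, the same adjusted over the list alone, with GDF15, the polo-like kinase PLK3 (1.66) and the cell cycle inhibitor CDKN1A (1.65, 172 to 538 TPM, adjusted p = 1.05e-06), at a relative median of 0.50 (fry adjusted p = 0.000187, adjusted p = 0.314 with an estimated correlation). Senescence and secretory genes rose in 7 of 13 and fell in 1 (9 and 2 adjusted over the list alone), with the stromelysin MMP10 at 2.33, at 0.60 (fry adjusted p = 9.84e-06, adjusted p = 0.314 with an estimated correlation). Apoptosis regulators rose in 8 of 18 and fell in 2, with PMAIP1 at 1.93 and BMF at -1.60 (fry adjusted p = 0.0136). The hypoxia response rose in 7 of 14, with ANGPTL4 at 1.06 (fry adjusted p = 0.0136). The ATF4 and hypoxia calls were lost with the replicate block (0.0642 and 0.0636), and the apoptosis and hypoxia calls in a fit of only the groups compared without a block (0.13 and 0.145). Of 20 antioxidant enzymes 6 rose and 1 fell (PRDX3 0.80, fry adjusted p = 0.247), and of 16 genes of the unfolded protein response 2 rose and 1 fell (HSPA5 0.50, fry adjusted p = 0.0859).

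Proliferation and biosynthesis genes were higher in FK866 than in DMSO at day 5. Of 33 DNA replication genes 30 were higher, the same adjusted over the list alone, with E2F1 (1.67, 11.4 to 36.8 TPM) and TYMS (1.63, adjusted p = 1.04e-05). The list had a relative median of 0.81 (fry adjusted p = 2.75e-05). Of 31 mitosis genes 27 were higher (28 adjusted over the list alone), as in UBE2C (1.70) and BIRC5 (1.44), at 0.99 (fry adjusted p = 3.11e-05). Ribosome biogenesis and MYC targets rose in 20 of 23, the same adjusted over the list alone, with ODC1 (1.77) and BOP1 (1.29), at 0.77 (fry adjusted p = 2.75e-05). Glycolysis genes rose in 17 of 21, as in PKM (1.42) and HK2 (1.31), at 0.74 (fry adjusted p = 0.000188). Pentose phosphate and NADPH genes rose in 8 of 15 (9 adjusted over the list alone), as in MTHFD2 (1.07) and TKT (0.99), at 0.50 (fry adjusted p = 0.000241). Cholesterol synthesis genes rose in 11 of 20 (12 adjusted over the list alone), as in DHCR7 (1.33), at 0.62 (fry adjusted p = 0.000221). For each of these 6 lists the estimated correlation gave adjusted p = 0.314. TCA cycle genes rose in 12 of 21 (14 adjusted over the list alone), as in SDHB (0.96) and MDH2 (0.89, fry adjusted p = 0.000581, adjusted p = 0.347 with an estimated correlation). The nuclear-encoded respiratory chain rose in 8 of 32, as in CYC1 (0.94) and ATP5F1B (0.91, fry adjusted p = 0.045), and this call was lost under median-of-ratios scaling (0.177). The replicate block ended the calls for glycolysis (0.0608), pentose phosphate and NADPH (0.0551), the TCA cycle (0.0608) and the respiratory chain (0.175). Of these only the respiratory chain also lost its call in the fit of the groups compared without a block (0.241). Among 12 genes of NAD synthesis and transport, NMRK1 fell (-1.10, adjusted p = 5.84e-05, 53.4 ± 7.36 to 24.3 ± 2.74 TPM) and no other member passed (fry adjusted p = 0.305). Among 15 NAD-consuming enzymes, PARP2, a DNA damage sensor, rose by 0.96 (adjusted p = 0.000689), and the list had a median of -0.02, a mean of 0.13 and no fry call (adjusted p = 0.32). Cytosolic ribosomal proteins had no calls among 22 in limma (fry adjusted p = 0.294).

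Vessel-type and matrix genes were lower in FK866 at day 5. Of 13 arterial genes 8 fell and 2 rose (8 and 3 adjusted over the list alone), led by ELN, the elastin gene (-2.65, adjusted p = 6.53e-07), GJA4 and SEMA3G, at a relative median of -0.99 (fry adjusted p = 0.000769, adjusted p = 0.314 with an estimated correlation). Venous and lymphatic genes fell in 2 of 7, LYVE1 (-1.78) and the VEGF receptor FLT4 (-1.18), at -0.57 (fry adjusted p = 0.00181, adjusted p = 0.314 with an estimated correlation). Extracellular matrix genes fell in 11 of 24, as in COL3A1 (-1.61) and NID1 (-1.49), at -0.60 (fry adjusted p = 0.00741, adjusted p = 0.347 with an estimated correlation). Interferon response genes fell in 7 of 22 and rose in 1 (8 and 1 adjusted over the list alone), with IFI44L at -1.08 and USP18 at 0.97, at -0.63 (fry adjusted p = 0.0156, adjusted p = 0.314 with an estimated correlation). Endothelial identity genes fell in 6 of 21 and rose in 1, with CD34 and FLT4 each at -1.18 and VWF, the von Willebrand factor gene, at -1.12 (3046 to 1405 TPM), at -0.39 (fry adjusted p = 0.015). Notch signalling fell in 6 of 14 and rose in 1, as in DLL4 (-1.55) and HEY1 (1.52, fry adjusted p = 0.026). The identity and Notch calls missed the threshold without the day 5 libraries numbered 1 (0.0659 and 0.0641), in a fit of fewer libraries. The list medians were of like size there, -0.38 for identity (-0.31 with all libraries) and -0.45 for Notch (-0.52). Endothelial junctions fell in 5 of 19, with GJA5 at -1.73, and the list missed the threshold (fry adjusted p = 0.0531). Tip cell and sprouting genes rose in 9 of 19 and fell in 3, with ESM1 (2.02) and the urokinase receptor PLAUR (1.72) up (fry adjusted p = 0.00356, adjusted p = 0.664 with an estimated correlation). In a fit of only the groups compared the arterial call held. Those for venous and lymphatic genes (0.078), tip cell genes (0.078), extracellular matrix (0.13), identity (0.13), the interferon response (0.137) and Notch (0.154) were lost, with unchanged medians.

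Transcript length was weighed for FK866 at day 5 as well, after the values were seen and without a test. Over 3 groups of genes from short to long transcripts the median change was 0.18, 0.12 and -0.03, and 0.27, 0.16 and -0.04 without the day 5 libraries numbered 1. Relative to genes of like length (10 groups by length), venous and lymphatic genes were at -0.37 and Notch signalling at -0.46, against -0.57 and -0.60 relative to all genes. Arterial genes were at -1.01, extracellular matrix at -0.51, the interferon response at -0.67 and endothelial identity at -0.38.

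Several lists moved in both directions at day 5 and had no fry call. FOXO targets rose in 4 of 16 and fell in 5, with PDK4, which restrains pyruvate oxidation, at -1.82 and CITED2 at 1.47 (fry adjusted p = 0.708). Cell cycle inhibitors rose in 4 of 15 and fell in 3, with CDKN1A up and CDKN1C (-1.46) down (fry adjusted p = 0.562). Shear and quiescence regulators rose in 1 of 14 and fell in 2, the clotting inhibitor TFPI (-1.30) and FOXO1 (-1.11), while KLF4 rose by 0.90 (fry adjusted p = 0.216). BMP and ALK1 signalling rose in 3 of 11 and fell in 1, with ID2 at 2.11 and BMP4 at -1.15, and had a median of -0.11 and a mean of 0.16 (fry adjusted p = 0.176). Inflammatory activation genes rose in 4 of 21 and fell in 4, with CXCL1 at 1.11 and CX3CL1 at -0.78 (fry adjusted p = 0.171). TGF-beta and mesenchymal genes rose in 7 of 17 and fell in 3, with ACTA2 at 1.74 and POSTN at -2.04 (fry adjusted p = 0.243). YAP and TAZ targets rose in 6 of 18 and fell in 1, with ANKRD1 at 1.48 (fry adjusted p = 0.0706). Lysosome and autophagy genes rose in 7 of 22 and fell in 1, with the lysosomal channel MCOLN1 at 0.78 and HEXA at -0.61 (fry adjusted p = 0.228).

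With FK866 present, day 5 was compared with day 2 to see how far the same transition went. AQP1 rose from 1.43 to 110 ± 45.6 TPM, by 5.45 ± 0.25 (SE, adjusted p = 4.05e-09), GJA4 by 3.80 (adjusted p = 9.92e-09) and IL33 by 3.71 (adjusted p = 2.9e-06). CD34, a sialomucin of endothelium, rose by 3.71 (adjusted p = 1.76e-09) and the fatty acid carrier FABP4 by 3.61 (adjusted p = 1.7e-09). TNFSF10 rose by 3.48, GDF3 by 3.41 and ACE by 3.14. Decreases were in HPDL (-2.12, adjusted p = 8.49e-06), UHRF1, which maintains DNA methylation at replication (-1.98, adjusted p = 7.86e-07), and the repressor E2F8 (-1.88). Others were in the serine synthesis enzyme PSAT1 (-1.73), the kinetochore gene SPC25 (-1.71), the polarity gene SAPCD2 (-1.69), the ribonucleotide reductase gene RRM2 (-1.69, adjusted p = 5.37e-07) and the chemokine CXCL6 (-1.66). NAMPT changed by 0.69 ± 0.26 (adjusted p = 0.0518), and by 0.92 without the FK866 library numbered 1 of day 5 (adjusted p = 0.0133). It passed too with the replicate block by description number (0.69, adjusted p = 0.0457) and in a fit of only the groups compared (adjusted p = 0.0397). In all, 3671 genes rose and 1198 fell, with 1151 and 250 at least 2-fold. Median-of-ratios scaling gave 3349 and 2469 and moved the median of all genes from 0.20 to 0.08.

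DNA replication fell in 31 of 33 in FK866 over time (33 adjusted over the list alone, relative median -1.33, fry adjusted p = 5.1e-06), and mitosis in 28 of 31, as in CCNA2 and CDC20, both at -1.52 (relative median -1.25, fry adjusted p = 1.82e-05, adjusted p = 0.102 with an estimated correlation). Ribosome biogenesis and MYC targets fell in 9 of 23 (RRS1 -1.22, fry adjusted p = 0.000448) and cholesterol synthesis in 5 of 20 (fry adjusted p = 0.0365), the latter call lost without the day 5 libraries numbered 1 (0.193, list median -0.22 against -0.21) and in a fit of only the groups compared (0.126). Of 22 p53 targets 17 rose and 1 fell (18 and 1 adjusted over the list alone), with GDF15 at 2.28 and FAS at 1.82 (relative median 1.04, fry adjusted p = 5.1e-06, adjusted p = 0.236 with an estimated correlation). Arterial genes rose in 10 of 13 (HEY1 2.54, fry adjusted p = 5.1e-06), Notch signalling in 10 of 14 (HES1 2.15, fry adjusted p = 1.42e-05) and FOXO targets in 13 of 16 (PDK4 2.43, fry adjusted p = 0.000448). Inflammatory activation genes rose in 14 of 21 with 4 falls (ICAM1 2.30, fry adjusted p = 2.87e-05), lysosome and autophagy in 15 of 22 (CTSD 1.29, fry adjusted p = 0.000361) and extracellular matrix in 13 of 24 (MGP 2.87, fry adjusted p = 0.000719). Endothelial identity rose in 9 of 21 (ANGPT2 2.73, fry adjusted p = 2.87e-05), with a relative median of 0.27. NRF2 targets rose in 5 of 18 and fell in 1 (FTL 0.97, fry adjusted p = 0.134), and the ATF4 and amino acid response rose in 7 of 24 and fell in 10 (ATF3 3.65, PSAT1 -1.73, fry adjusted p = 0.675). Glycolysis fell in 7 of 21 and rose in 1 (HK2 -0.90, fry adjusted p = 0.101).

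The change over time in FK866 was compared gene by gene with that in DMSO, which shares no library with it. Across the 14721 genes, which are not independent replicates, the log2 fold changes correlated at Pearson r = 0.80 and Spearman rho = 0.78, and the slope of FK866 on DMSO was 0.47. Of the 8638 genes called in DMSO, 7606 (88.1%) had the same sign in FK866, and 90.2% changed less in FK866. Selection by the DMSO change in itself favours a smaller change in FK866, so the 90.2% is no measure of the FK866 effect. Noise in the DMSO changes also lowers the slope. Calls in the same direction in both numbered 3896, against 1436.08 for independent lists, and calls in opposite directions 105, against 1420.96. MMP1 was among the exceptions. It fell by 2.30 in DMSO, while its mean went from 203 ± 26.1 to 547 ± 45.7 TPM in FK866. DKK1 went from 605 to 254 TPM in FK866, against 757 to 73.8 in DMSO.

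**Figure D3:**
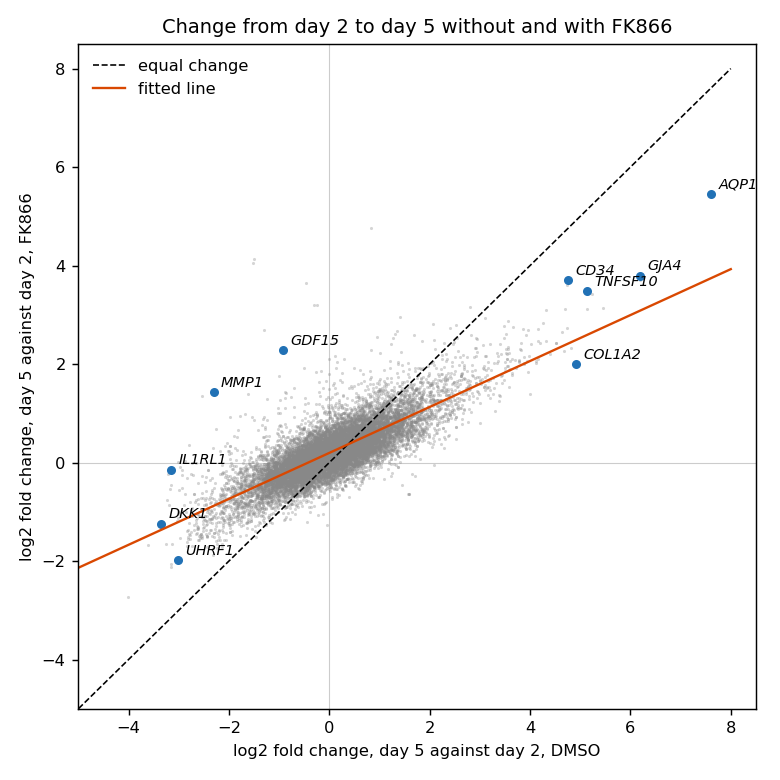
Log2 fold change from day 2 to day 5 of each gene in DMSO (horizontal axis) and in FK866 (vertical axis), one point per gene, with a dashed line of equal change and a fitted line of slope 0.47. AQP1, GJA4 and CD34 lie below the dashed line at the right, and MMP1 and GDF15 above it at the left.

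The FK866 effect at day 5 was then tested against that at day 2. Among genes that met the naming rule it differed most for MMP1 (3.73 ± 0.17, SE, adjusted p = 2.05e-08), GDF15 (3.20 ± 0.21, adjusted p = 5.46e-07), IL1RL1 (3.00, adjusted p = 5.46e-07), LNCOG (2.97, adjusted p = 6.61e-06) and PLEK2 (2.88, adjusted p = 0.000716), which were called for FK866 at day 5 and not at day 2. At day 2 the mean TPM of each was lower in FK866 than in DMSO, as in MMP1 (298 to 203) and LNCOG (48.9 to 33.2). Such a shift adds to the difference. The spread in this fit is shared with day 5, so a missing call at day 2 does not show that FK866 had no effect then. The FK866 effect differed the other way for COL1A2 (-2.91 ± 0.21, adjusted p = 2.36e-06), SEMA3G (-2.50, adjusted p = 0.000925), IL33 (-2.48, adjusted p = 0.00322), GJA4 (-2.40, adjusted p = 8.03e-05) and ACE (-2.31, adjusted p = 8.54e-05). In all, the difference was positive for 2186 genes and negative for 566, with 1033 and 317 at least 2-fold. Median-of-ratios scaling gave 1689 and 1745 and moved the median of all genes from 0.17 to -0.04. The number of calls was 6178 without the DMSO library numbered 1 of day 5 and 1817 without the FK866 library numbered 3 of day 5. Fry called 14 lists upward. Among them were NRF2 targets (10 of 18 genes up, OSGIN1 2.93, fry adjusted p = 0.000293), DNA replication (23 of 33, E2F1 2.00, fry adjusted p = 0.000251) and ribosome biogenesis (16 of 23, ODC1 1.78, fry adjusted p = 0.000133). Others were p53 targets (8 of 22 up and 2 down, CDKN1A 1.65, fry adjusted p = 0.00214) and the senescence list (6 of 13, fry adjusted p = 8.61e-05). It called 3 downward: arterial genes (5 of 13 down and 2 up, ELN -2.60, fry adjusted p = 0.0116), venous and lymphatic genes (2 of 7, LYVE1 -2.09, fry adjusted p = 0.0134) and extracellular matrix (6 of 24, fry adjusted p = 0.0365). The estimated correlation gave adjusted p = 0.425 for these. Relative to genes of like transcript length, without a test, the median of venous and lymphatic genes was -0.32, against -0.75 relative to all genes. Arterial genes were at -0.94 (-0.92) and extracellular matrix at -0.58 (-0.74). The respiratory chain (6 of 32 up) and apoptosis (7 of 18 up and 2 down) calls were lost under median-of-ratios scaling (0.147 and 0.343) and with the replicate block (0.0885 and 0.0568). In a fit of only the groups compared without a block these 2 (0.0699 and 0.077) and the extracellular matrix call (0.0699) were lost. TXNIP, up with FK866 at day 2, differed by -1.52 (adjusted p = 0.00043).

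NMN given with FK866 was compared with FK866 alone at day 5 to see what the product of the inhibited enzyme restores. No group had NMN without FK866, so an effect of NMN apart from the inhibition cannot be told from restoration. The NMN group also has no counterpart of the FK866 library numbered 1, which stood apart. MMP1 fell from 547 ± 45.7 to 68.2 ± 1.14 TPM (SD, n = 3), a log2 fold change of -2.98 ± 0.12 (SE, adjusted p = 3.54e-09), and GDF15 from 631 ± 38.7 to 84.5 ± 5.90 TPM (-2.89 ± 0.15, adjusted p = 1.39e-08). SEMA3G rose from 8.03 ± 3.39 to 80.5 ± 1.05 TPM (3.24 ± 0.29, adjusted p = 3.77e-06), and IL33 from 17.1 ± 10.2 to 140 ± 5.16 TPM (3.10 ± 0.35, adjusted p = 1.77e-05). Among genes that met the naming rule, the next largest falls were those of IL1RL1 (-2.66 ± 0.13, adjusted p = 1.39e-08), PLEK2 (-2.60 ± 0.32, adjusted p = 3.59e-05) and FOSL1 (-2.59 ± 0.21, adjusted p = 1.96e-06), followed by the neuropeptide gene GAL (-2.48 ± 0.28, adjusted p = 1.93e-05), KRT7 (-2.44 ± 0.28, adjusted p = 2.01e-05, 423 to 73.6 TPM) and LNCOG (-2.37 ± 0.18, adjusted p = 1.12e-06). The next largest rises under that rule were those of ABLIM1, an actin-binding protein (2.52 ± 0.33, adjusted p = 5.79e-05), GJA4 (2.46 ± 0.19, adjusted p = 1.44e-06) and MATN2 (2.45 ± 0.27, adjusted p = 1.66e-05). Next were AQP1 (2.40 ± 0.25, adjusted p = 9.01e-06), COL1A2 (2.40 ± 0.15, adjusted p = 2.2e-07) and ACE (2.35 ± 0.19, adjusted p = 1.66e-06). In all, 5131 genes rose and 1474 fell, with 1723 and 340 at least 2-fold. Median-of-ratios scaling gave 3614 up and 3172 down and moved the median of all genes from 0.29 to 0.05, with 5087 genes called in the same direction under both. Removal of the ribosomal RNA genes gave 4609 and 2361 and left the median of all genes at 0.23. Without the day 5 libraries numbered 1 there were 7489 calls, with 6263 genes called in the same direction as in the main fit.

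Stress, proliferation and biosynthesis lists fell when NMN was added. NRF2 targets fell in 8 of 18 and rose in 2 (10 and 2 adjusted over the list alone), as in OSGIN1 (-2.43) and HMOX1 (-1.70), at a median of -0.89 relative to all genes (fry adjusted p = 0.000774, adjusted p = 0.248 with an estimated correlation). DNA replication fell in 21 of 33 (23 adjusted over the list alone), as in E2F1 (-1.53) and CDT1 (-1.39), at -0.93 (fry adjusted p = 0.000309). Mitosis fell in 21 of 31, as in UBE2C (-1.65) and BIRC5 (-1.27), at -0.88 (fry adjusted p = 0.000714). Ribosome biogenesis fell in 14 of 23 (15 adjusted over the list alone), as in ODC1 (-1.40) and BOP1 (-1.34), at -0.78 (fry adjusted p = 0.000575). Each of these 3 had adjusted p = 0.248 with an estimated correlation. Senescence and secretory genes fell in 7 of 13 and rose in 3, with MMP10 at -1.99 and CXCL8 at -1.89 (fry adjusted p = 8.78e-05, adjusted p = 0.333 with an estimated correlation). Glycolysis fell in 14 of 21 and rose in 1, as in PKM (-1.34) and ENO1 (-1.04, fry adjusted p = 0.00262). The p53 targets fell in 10 of 22 and rose in 3, as in CDKN1A (-1.39) and TP53INP1 (1.79, fry adjusted p = 0.00564), a call lost with the replicate block (0.051). Pentose phosphate and NADPH genes fell in 4 of 15, as in MTHFD2 (-0.80, fry adjusted p = 0.0352). The ATF4 and amino acid response fell in 8 of 24 and rose in 5, with ATF3 at -3.82 and DDIT4 at 1.18 (fry adjusted p = 0.0384). These last 2 calls missed the threshold without the day 5 libraries numbered 1 (0.0625 and 0.0591), in a fit of fewer libraries, while the list medians were -0.25 (-0.23 with all libraries) and -0.21 (-0.15). TCA cycle genes fell in 4 of 21 (MDH2 -0.87, fry adjusted p = 0.0636), cholesterol synthesis in 4 of 20 (DHCR7 -0.90, fry adjusted p = 0.0859) and the respiratory chain in 4 of 32 (CYC1 -0.83, fry adjusted p = 0.191).

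Endothelial, matrix and interferon lists rose with NMN. Endothelial identity rose in 15 of 21 and fell in 1, the same adjusted over the list alone, with MMRN1 at 1.73 and FLT4 at 1.59, at a relative median of 0.52 (fry adjusted p = 0.000349, adjusted p = 0.489 with an estimated correlation). VWF went from 1405 to 3937 TPM. Endothelial junctions rose in 14 of 19 (15 adjusted over the list alone), with GJA5 at 2.38 and AFDN at 1.34, at 0.62 (fry adjusted p = 0.000531). Arterial genes rose in 8 of 13 and fell in 2, with ELN at 2.29, at 0.66 (fry adjusted p = 0.000126). Venous and lymphatic genes rose in 6 of 7, with LYVE1 at 2.05 (fry adjusted p = 0.000111). Notch signalling rose in 8 of 14 with 1 fall, as in EFNB2 (2.11) and DLL1 (1.93, fry adjusted p = 0.000202). Interferon response genes rose in 17 of 22 and fell in 1, as in XAF1 (1.82) and IFIT2 (1.74), at 0.94 (fry adjusted p = 0.000111, adjusted p = 0.445 with an estimated correlation). Extracellular matrix rose in 18 of 24 (20 adjusted over the list alone), with NID1 at 2.14 (fry adjusted p = 0.000349). Shear and quiescence regulators rose in 10 of 14 with 1 fall, as in FOXO1 (1.83) and TFPI (1.68, fry adjusted p = 0.0029), a call lost with the replicate block (0.0972). Of 12 genes of NAD synthesis and transport 5 rose (4 adjusted over the list alone), as in NMRK1 (1.38, adjusted p = 7.76e-06) and the transhydrogenase NNT (1.07, adjusted p = 0.0164), with fry adjusted p = 0.004. The median of that list was 0.02 relative to all genes, of which 5131 of 14721 rose, and 0.11 relative to genes of like transcript length (0.20 without the day 5 libraries numbered 1). FOXO targets rose in 10 of 16 and fell in 3 (PDK4 2.31, fry adjusted p = 0.0267), and NAD-consuming enzymes rose in 4 of 15 and fell in 1 (SIRT5 0.67, fry adjusted p = 0.039). Both of these calls were lost under median-of-ratios scaling (0.127 and 0.0906), and that for FOXO targets also in a fit of only the groups compared, without (0.0971) and with the replicate block (0.166). Among lists without a fry call, cell cycle inhibitors rose in 7 of 15 and fell in 3 (CCNG2 1.55), tip cell and sprouting genes rose in 6 of 19 and fell in 8 (PLAUR -1.86), and apoptosis regulators rose in 4 of 18 and fell in 7 (BMF 2.09, PMAIP1 -1.46).

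The change with NMN against FK866 also followed transcript length. Over 3 groups of genes from short to long transcripts its median was 0.0003, 0.25 and 0.55, and 0.05, 0.19 and 0.38 without the day 5 libraries numbered 1. The list tests are not adjusted for length, so list medians were set against genes of like length (10 groups by length), a comparison chosen after the values were seen and made without a test. Endothelial identity was then at 0.48, junctions at 0.48, arterial genes at 0.67, Notch signalling at 0.46, extracellular matrix at 0.44 and the interferon response at 0.94. Venous and lymphatic genes went from 0.48 relative to all genes to 0.13, and NAD-consuming enzymes from 0.14 to -0.03. NRF2 targets were at -0.85, DNA replication at -0.83 and mitosis at -0.81, while p53 targets went from -0.65 to -0.40.

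**Figure D4:**
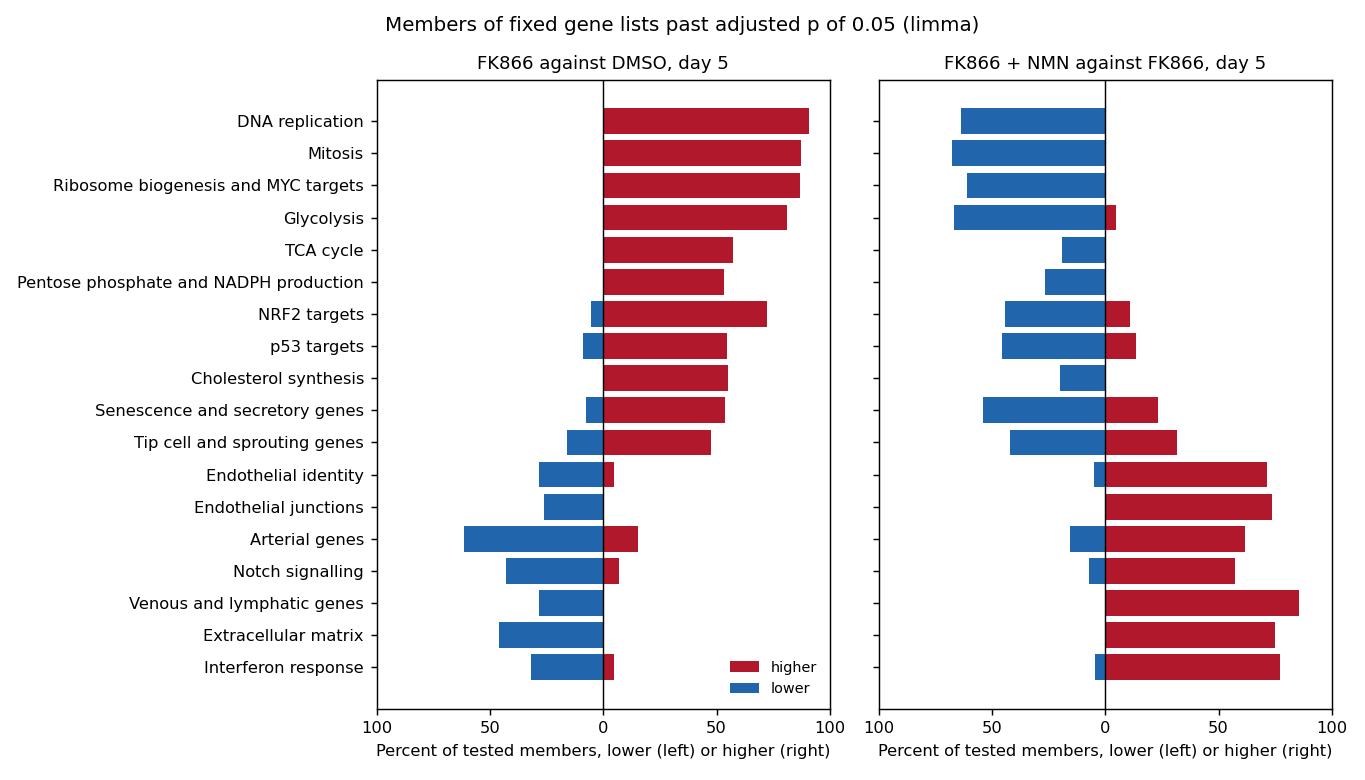
Percent of tested members of 18 gene lists that were higher (right, red) or lower (left, blue) at an adjusted p under 0.05, for FK866 against DMSO (first panel) and FK866 with NMN against FK866 (second panel) at day 5. DNA replication genes were higher in FK866 in 30 of 33 and lower with NMN in 21 of 33, directions that median-of-ratios scaling did not reverse.

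Of the 3971 genes called for FK866 at day 5, 2723 (68.6%) were called in the opposite direction when NMN was added, against 738.446 for independent lists, and 16 (0.403%) were still called in the FK866 direction in FK866 with NMN against DMSO. The FK866 libraries enter both comparisons, so that their chance deviations enter with opposite signs. In simulated data with the same sharing, NMN without effect gave a median of 0 opposite calls (highest 1) by limma, and NMN returning every gene to its DMSO mean gave 79.5%. These simulations gave each gene the same spread in every group and called more genes for FK866 (medians of 5038 and 5029). Their values are thus no firm yardstick for the observed share. Median-of-ratios scaling raised the share to 90.0% (4399 of 4889), and without the day 5 libraries numbered 1 it was 63.3%, with 1469 genes still called against DMSO. Those 1469 depend on the scaling. With median-of-ratios scaling, FK866 with NMN against DMSO had 71 calls in all without these libraries, and 3 with all libraries. In the deposited scaling the number still called also hung on single DMSO libraries: it was 1620 of 3777 without the DMSO library numbered 5 and 172 of 6416 without the DMSO library numbered 1.

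FK866 with NMN was also compared with DMSO at day 5, where full restoration would leave no difference. Among genes that met the naming rule the largest increase was in TXNDC5, a disulfide isomerase of the endoplasmic reticulum, from 87.0 ± 23.6 to 253 ± 62.3 TPM (SD, n = 3), by 1.53 ± 0.20 (SE, adjusted p = 0.0136). The others that met the naming rule were AMOTL2, an angiomotin-like regulator of YAP (0.92, adjusted p = 0.0476), the pseudokinase NRBP2 (0.87, adjusted p = 0.0311), and the splicing factor HNRNPH1 (0.85, adjusted p = 0.047). They also included the chemokine CXCL2 (0.84, adjusted p = 0.047), the RNA helicase DDX5 (0.81, adjusted p = 0.0493), the GABA receptor subunit GABBR1 (0.79, adjusted p = 0.047) and the RNA processing factor LENG8 (0.78, adjusted p = 0.047). All 90 called genes were higher with NMN, and 6828 genes had an unadjusted p under 0.05. Ribosomal RNA genes took 4.70% of the TPM with NMN and 18.0% in DMSO. Their removal moved the median of all genes from 0.36 to 0.16 and left 7 calls, all up, so they account for only part of that shift. Median-of-ratios scaling moved the median to 0.00 and left 3 calls (1 up, 2 down). Only 1 of the 90 calls was kept under that scaling. TXNDC5 was then at 1.12 (adjusted p = 0.0632, limma) and AMOTL2 at 0.51 (adjusted p = 0.426, limma). A fit of only the groups compared gave 0 calls in limma (3568 genes at an unadjusted p under 0.05). Leaving out single libraries gave 0 calls in limma without the DMSO library numbered 4 or the NMN libraries numbered 4 and 5 (5224, 4050 and 4598 genes at an unadjusted p under 0.05). It gave 1 call without the NMN library numbered 6, 673 without the DMSO library numbered 1 and 7694 without the DMSO library numbered 5. Fry called 28 of 36 lists upward, each with adjusted p = 0.984 with an estimated correlation, and after median-of-ratios scaling it called 4 (1 up, 3 down). Few list members passed: CXCL2 of 21 inflammatory genes, and 2 of 18 YAP and TAZ targets, AMOTL2 among them. Relative to all genes the medians were -0.02 for NAD synthesis and transport, -0.06 for DNA replication, -0.08 for NRF2 targets, 0.27 for the interferon response and 0.28 for endothelial junctions.

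Markers of other cell types were examined beside these lists, as far as they are analysed here. The 3 fibroblast markers tested were all collagen genes, so no other marker shows whether fibroblasts contributed. COL1A2 and COL3A1 fell with FK866 at day 5 (-2.90 and -1.61) and rose with NMN (2.40 and 1.60), while COL1A1 changed by 0.37 (adjusted p = 0.64) and -0.39 (adjusted p = 0.559). Mural cell markers moved apart. ACTA2 (1.74) and RGS5 (0.96, adjusted p = 0.00618) rose with FK866 at day 5, while PDGFRB (-1.19) and NOTCH3 (-1.13, adjusted p = 0.00525) fell, and each went the other way with NMN. Of 5 epithelial markers, KRT18, a keratin also made by cultured endothelial cells, rose with FK866 (1.11, adjusted p = 0.00707) and fell with NMN (-1.26, adjusted p = 0.00203), and EPCAM changed by 0.11 (adjusted p = 0.755) and -0.20 (adjusted p = 0.5). The leukocyte markers LYZ and CD74 did not pass with FK866 (0.38 and -0.32) or with NMN (0.17 and 0.25).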

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

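The tests of less advanced cultures, and of the time course without the libraries numbered 1 and after median-of-ratios scaling, were chosen after the results they measure had been seen.

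The effect of FK866 differed between day 5 and day 2 for 2752 genes, by a test of the difference itself, with MMP1 at 3.73 and COL1A2 at -2.91. It differed for 17 gene lists by fry, 14 upward and 3 downward. Of 100 splits of the 12 DMSO and FK866 libraries within each day, 5 gave as many genes, the real one included, and the highest other gave 6108, so chance is not excluded by this count. That split kept the real groups at day 2 and set the DMSO library numbered 1 with the FK866 libraries numbered 1 and 3 at day 5, and its count, far above the real one, points to a structure of the day 5 libraries. For FK866 against DMSO at day 5, 2 of 10 splits gave at least the real 3971 genes. The highest other, 6790, was that same division of the day 5 libraries. In the other 5 comparisons 1 of 10 splits, the real one, gave the real count, and 10 splits are too few for a share under 0.05. There limma called 0 genes in the highest other split. Every other split mixes the real groups, so a real difference between them widens the spread and lowers the calls. The low counts in other splits are thus partly built in and lend the real counts no support. The real split called 5 for FK866 against DMSO at day 2, 6605 for NMN against FK866, 90 for NMN against DMSO, 8638 for time in DMSO and 4869 for time in FK866. At an unadjusted p under 0.05 the most in any other split were, in that order, 152 (1467 in the real split), 1215 (7849), 2204 (6828), 3855 (9274) and 1285 (6288).

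The first pattern is that the day 5 libraries numbered 1 stand apart from the others of their group, in DMSO and in FK866 alike. Their deviations from the other libraries of the group correlated across genes at r = 0.913 between the treatments. Their share of ribosomal RNA was the lowest of the group, 6.60% against 32.4% and 15.2% in DMSO and 5.67% against 9.59% and 10.4% in FK866. That difference in share is argued against as the cause, since the median absolute deviation without those genes was 1.02 times that with them. A transcript length bias has the values it needs: Spearman's rho of the deviation with transcript length was -0.51 in DMSO and -0.51 in FK866, and the median deviation in DMSO went from 0.44 in the shortest transcripts to -0.56 in the longest. A difference in RNA integrity or library preparation could give such a trend, and neither was measured here. Cultures less advanced towards the day 5 state could give part of it and cannot be told apart here, because the correlation of the deviation with the change from day 2 to day 5 (r = -0.43 in DMSO and -0.47 in FK866) fell between the bounds of -0.5 and -0.2 set for and against it.

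The second pattern is that genes changed from day 2 to day 5 in FK866 by a fraction of their change in DMSO, a slope of 0.47. The libraries numbered 1 are argued against as the cause, since the slope without them was 0.458. Transcript length bias is argued against as well, with slopes between 0.465 and 0.507 within groups of genes of like length. The slope after median-of-ratios scaling, 0.477, decides nothing about the scaling of the libraries, because a factor per library shifts all genes nearly alike and leaves a slope as it is. A partial transition to the day 5 state under NAMPT inhibition stays open as a hypothesis, as does a slower increase in cell density with the same genes, and neither was tested. Noise in the DMSO changes lowers such a slope too, by an amount that was not measured here.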

How the results depend on the processing

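Median-of-ratios scaling, removal of ribosomal RNA genes, leaving out the day 5 libraries numbered 1, their combinations, a minimum of 5 TPM and, for gene lists, the fit of only the groups compared were chosen after seeing the data. So was the count of lists called for FK866 with NMN against DMSO, which replaced the single lists of that comparison after most were seen to lose their call or change sign under median-of-ratios scaling. Where no construction is named, the cause was not tested.

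For FK866 against DMSO at day 2 (5 genes), a pseudocount of 0.5 gave 3 and the 1.5-fold test 0 (34 at an unadjusted p under 0.05, limma). A fit of only the groups compared, which drops the wider spread of day 5, gave 2530, and 4540 with median-of-ratios scaling. Scaling by median of ratios gave 134, removal of ribosomal RNA genes 41, leaving out the day 5 libraries numbered 1 1543, and this with scaling 3772. Each library left out gave 0, with unadjusted counts of 982, 904 and 975 (DMSO 1, 2 and 3) and 800, 1030 and 1682 (FK866 1, 2 and 3). TXNIP and EGR1 lost their call each time (adjusted p 0.0863 to 0.34).

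For FK866 against DMSO at day 5 (3971), the 1.5-fold test gave 449, only the groups compared 687, this with scaling 1127, leaving out the libraries numbered 1 5992, and this with scaling 8001. Single libraries left out gave 2638 (FK866 number 3) to 6416 (DMSO number 1). For NMN against FK866 (6605) the 1.5-fold test gave 859, and no other alternative moved the count by more than 1.5 times. For NMN against DMSO (90), pseudocounts of 0.1 and 0.5 gave 3 and 10, no trend 31, the 1.5-fold test 0 (45 unadjusted, limma), only the groups compared 0 (3568), this with scaling 0 (445), scaling 3, removal of ribosomal RNA genes 7, a minimum of 5 TPM 7, leaving out the libraries numbered 1 4701, and this last with scaling 71 (53 up, 18 down). Without single libraries it ranged from 0 (DMSO 4, NMN 4 and NMN 5, with 5224, 4050 and 4598 unadjusted) through 1 (NMN 6) and 673 (DMSO 1) to 7694 (DMSO 5).

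For day 5 against day 2 the 1.5-fold test gave 3340 in DMSO (8638) and 752 in FK866 (4869), where leaving out the libraries numbered 1 gave 7772 and this with scaling 9287. For the difference of FK866 effects (2752) the 1.5-fold test gave 276, only the groups compared 1783, leaving out the libraries numbered 1 6242 and this with scaling 8150, and single libraries 1817 (FK866 number 3 of day 5) to 6178 (DMSO number 1 of day 5). The slope of time in FK866 on DMSO (0.466) ranged from 0.387 (without DMSO number 1 of day 5) to 0.512 (without FK866 number 1 of day 5), with 0.409 without FK866 number 4. The share of FK866 calls that NMN reversed (68.6%) ranged from 56.6% (without DMSO number 5) to 99.1% (only the groups compared). The genes still called against DMSO (16) came to 1620 of 3777 without DMSO number 5, 172 of 6416 without DMSO number 1 and at most 16 without any other library.

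NAMPT between day 2 and day 5 in DMSO went from -0.04 to 0.36 (adjusted p = 0.00458) under median-of-ratios scaling without the libraries numbered 1, the 1 named result that reversed. Of 91 results for named genes, 83 kept direction and side of the threshold under scaling, 85 without ribosomal RNA genes and 88 without the libraries numbered 1. Over all single libraries left out, 565 values for named genes kept both, 43 lost the call and 4 gained it. NAMPT passed for FK866 at day 5 without DMSO number 5 (0.79, adjusted p = 0.0378) or FK866 number 1 (0.79, adjusted p = 0.0386), and with the replicate block by description (adjusted p = 0.0158) or title number (0.0243), and over time in FK866 with the former (0.0457). Of 109 single list results called by fry, 104 kept their call under scaling, 106 without ribosomal RNA genes, 91 in a fit of only the groups compared, 70 in that fit with the replicate block (which lost every list called over time in DMSO) and none by camera (lowest adjusted p = 0.0996). For NMN against DMSO fry called 28 lists, 4 under scaling, 1 without ribosomal RNA genes and none in a fit of only the groups compared, with or without the block.

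The labels do not say that replicate numbers pair libraries. The deviations of DMSO and FK866 libraries of the same number correlated at 0.0004, 0.196 and 0.3 at day 2. At day 5 they correlated at 0.913 and 0.815 by title number (1 and 4) and at 0.913, 0.098 and 0.854 by description number. Libraries whose numbers differ reached 0.854 at day 5 by title and 0.815 by description number, so these values do not settle a pairing. In DMSO the day 2 and day 5 libraries of the same description number correlated at -0.118, 0.475 and -0.557. These mixed signs give no sign of a pairing over time. The block was fitted to only the groups compared, so its counts are set against that fit without a block. It gave 2607 genes against 2530 for FK866 at day 2, 5024 by description number and 2661 by title number against 687 for FK866 at day 5, 5648 against 7028 for NMN against FK866, and 126 and 110 against 0 for NMN against DMSO (3568 unadjusted, limma). Over time it gave 6394 against 6992 in DMSO and 3484 and 3776 against 4414 in FK866, and 1906 against 1783 for the difference of effects. With the block 9 genes were still called against DMSO in the FK866 direction. Count-based tests were not run, since TPM holds no counts, and scaling by library size alone equals the deposited scaling. Depth is unknown.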

Other observations

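The count at a stricter threshold was chosen after the result was seen. The tests of a delay, of scaling and of the libraries that stood apart were fixed before it. The test of list enrichment is not counted as fixed beforehand, since it was made on a set of genes taken from these data.

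In FK866 at day 5, 299 genes were higher than in both FK866 at day 2 and DMSO at day 5, and 5 were lower than in both. The p53 targets were the most enriched, with 10 of 22 tested members against 2.03% of all genes (one-sided Fisher's exact test, adjusted p = 1.93e-10 over 36 lists). They were CDKN1A and GADD45A, which stop the cell cycle, MDM2, the ligase that degrades p53, the death receptor FAS, the stress cytokine GDF15, SESN2, TP53I3, PLK3, FDXR and PHLDA3. CDKN1A was at 199 TPM in FK866 and in DMSO at day 2, at 172 in DMSO and 538 in FK866 at day 5, and at 205 with NMN. Lysosome and autophagy genes followed with 5 of 22 (adjusted p = 0.00119, exact), among them the channel MCOLN1, the receptor SQSTM1, MAP1LC3B and the proton pump subunit ATP6V1H. Senescence and secretory genes had 4 of 13 (adjusted p = 0.00124, exact), which were CDKN1A, MMP1, MMP10 and GDF15. Hypoxia genes had 3 of 14 (NDRG1, P4HA2 and ANGPTL4, adjusted p = 0.023, exact), NRF2 targets 3 of 18 (HMOX1, OSGIN1 and FTL, adjusted p = 0.0324, exact), apoptosis regulators 3 of 18 (adjusted p = 0.0324, exact) and tip cell genes 3 of 19 (adjusted p = 0.0325, exact). No gene of the DNA replication, mitosis or endothelial identity lists was above both. With 33, 31 and 21 tested members and 2.03% of all genes above both, a count of 0 can well arise by chance. The test treats genes as independent, and CDKN1A and GDF15 are in both the p53 and the senescence list.

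A delayed time course in which each gene moves one way from day 2 to day 5 would leave FK866 at day 5 between the other groups. At an adjusted p under 0.01 in both comparisons 143 genes remained above both, where the threshold allows 38.47 false calls. That bound holds only if the adjusted p keeps its rate. The 6790 calls in a mixed split of the day 5 DMSO and FK866 libraries put this in doubt. The count was also made in the deposited scaling alone. It therefore does not settle whether a delay of that kind is the whole cause. A delay as such cannot be told apart here, because a gene that rises for a time between the days would lie above both groups in a delayed culture, and only 2 days were sampled. The bound set beforehand, met by 299 genes against at most 22 (median 14) in simulated data, assumed that each gene moved by the fitted fraction of its DMSO change, a profile the design cannot check. The libraries numbered 1 are argued against as the cause of the genes above both, with 626 without them. So is scaling, with 251 after median-of-ratios scaling. The excess of genes above both over genes below both did depend on scaling. Median-of-ratios scaling raised those below both from 5 to 119. Without the libraries numbered 1 as well, 453 genes were above both and 303 below. The list enrichments were not repeated under that scaling. Leaving out single libraries gave from 175 genes above both (without the FK866 library numbered 3 of day 5) to 702 (without the DMSO library numbered 1 of day 5). A stress response to NAMPT inhibition that comes on after day 2 stays open beside a delay, with or without such transient genes. No protein or NAD level was examined here to test it.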
